A study of Homo sapiens with 12 samples.

How the data were processed

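RNA abundance was measured in MCF-7 cells with Affymetrix HG-U133 Plus 2 arrays, which hold short oligonucleotide probes grouped into probe sets. Per the labels' protocols, cells were plated 48 h before treatment and treated for 24 h, total RNA was extracted with a column kit, and biotin-labelled RNA was made by amplification before hybridisation. The 12 arrays fall into 4 groups of 3: vehicle (ethanol), 17β-estradiol (E2, 1 nM), 27-hydroxycholesterol (27HC, 1 µM) and both compounds. The labels number 3 batches, and each batch holds 1 array of every group, so that replicates 1 to 3 of a group are its arrays in batches 1 to 3. They do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may in part be technical.

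The deposited values are log2 expression levels per probe set, which the authors made by robust multi-array averaging (RMA) with affy 1.36.1, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each set. The deposited log2 values ran from 1.80 to 14.4, with 0 missing. Array medians lay between 4.61 and 4.72 and the SDs of the arrays between 2.33 and 2.40. RMA shrinks differences between low signals, so changes of genes near the bottom of the range are understated. Where the lower group's mean of a named gene lay less than 0.1 log2 above the lower quartile of its arrays, only a lower bound of the fold is given, by a rule chosen after the levels were seen. It sets the higher group's mean against, per array, the higher of that array's lower quartile and the gene's own level. Such a bound allows for shrunken low signals but not for the spread between arrays, so single batches can lie below it. There is no read depth: the number of arrays limits the precision, and the median standard error of a difference between 2 groups was 0.0987 on the log2 scale.

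Of 54675 probe sets, 41097 named exactly 1 gene symbol in the platform annotation, 1801 named several and 11777 named none. The Entrez numbers of 41043 of the first kind were found in a RefSeq gene table, which changed 0 symbols. Each gene was represented by its probe set with the highest mean over the 12 arrays, which gave 19775 genes. No filter on low values was applied. No coordinates are given, because the sources used here name no genome build.

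The values were tested with limma 3.58.1 in R 4.3.3. lmFit fitted the 4 group means over all 12 arrays, so that the groups shared 1 estimate of the spread, and eBayes gave moderated two-sided p-values, which were adjusted with the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05. The contrasts were 27HC against vehicle, E2 against vehicle, both compounds against E2, both compounds against 27HC, 27HC against E2, and the interaction, which is the 27HC difference with E2 minus that without E2.

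The 17 gene lists were fixed before the data were examined, as were the main design, the rule for named genes and most of the other settings tried. They held 369 symbols, of which 339 were measured, and covered genes known to be induced or repressed by estrogen, DNA replication, mitosis, liver X receptor (LXR) targets, cholesterol synthesis, fatty acid synthesis, oxysterol and bile acid enzymes, nuclear receptors and coregulators, the unfolded protein response, epithelial and mesenchymal genes, hypoxia and glycolysis, the interferon response, p53 targets, retinoid and aryl hydrocarbon responses, and markers of other cell types. The 30 other symbols, among them HMGCR, LDLR, PCSK9, AR and STAT1, were not analysed here. Lists were compared with all other genes by limma's camera at its preset correlation of 0.01 between genes, adjusted over the 17 lists of a contrast. The same test with a correlation estimated from the data, and fry, which asks whether a list's genes move 1 way without comparing them with other genes, served as alternatives.

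Named genes were chosen by a rule. For 27HC against vehicle, E2 against vehicle, and both compounds against E2 and against 27HC, it took the 6 largest rises and 6 largest falls among genes called changed with the same sign in all 3 batches. For the interaction and for 27HC against E2 it took 4 of each. From each list with a call or at least 2 changed members it took up to 4 members with the smallest adjusted p. It added GREB1, TFF1, PGR, CXCL12, ESR1, ABCA1, ABCG1, MYLIP, HMGCS1 and INSIG1 where they helped. Genes sharing a probe set with another symbol were not named. No gene named by the rule had probe sets called in opposite directions.

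The labels call the replicate number a batch, so the number pairs arrays across groups. After the group means were removed, the 18 pairs of arrays from the same batch had a median correlation of 0.253 across genes (range 0.0671 to 0.55), and the 36 pairs from different batches had one of −0.146 (−0.47 to 0.2). Each of the 12 arrays correlated best with an array of its own batch. The batch as a block in the fit was one of the other settings tried.

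Other settings fixed at that time used only the arrays compared, eBayes with an intensity trend and robust prior, genes at or above the median level or at or above a mean log2 of 6, arrays centred on their medians, a second quantile normalization, every probe set, the mean of a gene's probe sets, array weights, a minimum fold of 1.2, and the data without each array in turn. Settings chosen after the data were seen were the block together with an estimated correlation, the block without each batch, the 2 rescalings for the gene lists, the quantile normalization for the correlations, a 27HC contrast averaged over both backgrounds, genes chosen in 2 batches and measured in the batch left out, and the 32 swaps of the 27HC labels within batches. Where the fit without 1 array left a group with 2, the shared spread of all groups was used.

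Technical probe sets (hybridisation controls, poly-A controls and the 3' minus 5' signal of ACTB and GAPDH) and the array SD were compared between arrays with and without 27HC, and with and without E2, by exact two-sided permutation tests over the 924 splits, adjusted over 10 tests, and, added after these were seen, by exact sign flips of the 6 pairs of arrays from a batch. An exact comparison of 3 arrays with 3 cannot give a p below 0.1. The procedures were tested on simulated data in which 200 of 19775 genes were changed. For 27HC against vehicle the fit recovered 70.1% of genes changed by 0.5 log2, 94% of those changed by 1 and 100% of those changed by 2, with 9 false calls among 185. For both compounds against E2 the shares were 59.7%, 98.5% and 100%, with 11 false calls among 183. For the interaction they were 26.9%, 92.5% and 100%, with 5 false calls among 151. The simulation drew each gene independently and held no shift shared by the arrays of a batch, unlike the measured data. The shares recovered therefore do not measure the sensitivity reached on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.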

Results

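Gene expression was measured in MCF-7 cells, a human breast cancer line that carries the estrogen receptor and grows in response to estrogen. The cells received ethanol vehicle, 17β-estradiol (E2) at 1 nM, 27-hydroxycholesterol (27HC) at 1 µM, or both compounds, for 24 h. E2 is the main ligand of the estrogen receptor. 27HC is a cholesterol metabolite made by CYP27A1 that binds both the estrogen receptor and the liver X receptors (LXR). Each of the 4 groups held 3 arrays, 1 from each of 3 labelled batches, and 19775 genes were measured on a log2 scale. The median array level lay between 4.61 and 4.72 in every sample.

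The comparison of E2 with vehicle asked what estrogen alone did to these cells. EGR3, an early-response transcription factor, rose 18-fold, from 4.11 ± 0.49 to 8.28 ± 0.45 log2 units (SD, n = 3 arrays per group). The progesterone receptor gene PGR rose 6.01-fold, from 7.53 ± 0.27 to 10.12 ± 0.21, and the chemokine gene CXCL12 rose 4.10-fold (log2 change 2.03 ± 0.078, SE). The interleukin receptor gene IL1R1 was at least 9.56-fold lower (adjusted p = 1.3e-07), its level with E2 lying near the lower quartile of array levels. Of the 2 probe sets of IL1R1, 1 was called when each was tested on its own (log2 differences −3.26 to −0.096). All 38 measured DNA replication genes and all 35 measured mitosis genes were called higher by limma.

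Of the 33 measured genes known to be induced by estrogen, 30 rose and 1 fell (30 and 2 adjusted over the list alone), and the median log2 change of the list was 1.40 (adjusted p = 1.25e-28, and 0.00028 with an estimated correlation). RET, a receptor tyrosine kinase, rose by 1.68 ± 0.076 (SE), RAPGEFL1 by 1.64 ± 0.078 and the cadherin-family gene CELSR2 by 1.45 ± 0.074. GREB1 and TFF1, commonly used reporters of estrogen receptor activity, rose 3.44-fold and 2.64-fold. Of 20 genes known to be repressed by estrogen, 17 fell (18 adjusted over the list alone), with a list median of −1.15 (adjusted p = 2.99e-16, 0.018 with an estimated correlation, and 0.11 with both an estimated correlation and the batch block). Besides IL1R1 these included PNRC1, a nuclear receptor coactivator gene (−1.22 ± 0.088), YPEL3, a growth suppressor (−1.17 ± 0.094), and CCNG2, an atypical cyclin linked to cell cycle arrest (−1.17 ± 0.10).

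The DNA replication list moved by a median of 1.36 (adjusted p = 2.06e-30, and adjusted p = 0.18 with an estimated correlation). FEN1, a flap endonuclease, rose by 1.43 ± 0.13, E2F2 by 1.40 ± 0.14 and LIG1, a DNA ligase, by 1.21 ± 0.13. The mitosis list moved by a median of 1.68 (adjusted p = 6.04e-27, and adjusted p = 0.19 with an estimated correlation). KIF23 and KIF11, mitotic kinesins, rose by 1.90 ± 0.21 and 1.67 ± 0.20, and FOXM1, a transcription factor of the G2/M programme, by 1.72 ± 0.22. Adjusted over the list alone, all 38 and all 35 genes were called as well.

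Among the other largest changes, MYBL1 rose 13.8-fold, the cadherin CDH26 10.6-fold, the scaffold gene PDZK1 9.57-fold, the RNA-binding protein gene RBM24 7.05-fold and SDK2 6.03-fold. With every probe set tested on its own, 1 of 3 for MYBL1 was called (log2 differences 0.0221 to 3.78). For CDH26 it was 2 of 4 (−0.0946 to 3.41) and for SDK2 3 of 5 (0.0511 to 2.59). AHRR, a repressor of the aryl hydrocarbon receptor, was 8.28-fold lower, the Wnt ligand gene WNT2B 7.33-fold, ASB9 5.42-fold, CSTA 4.99-fold and the cyclin-dependent kinase gene CDK6 4.87-fold. Limma called 4260 genes changed, 2169 higher and 2091 lower, which was 21.5% of those tested, and 406 rose and 203 fell at least 2-fold. The sign was the same in all 3 batches for 4257 of the 4260. Calling genes on the same arrays favours such agreement, here and in the comparisons below, so it adds no separate support.

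Genes of cholesterol synthesis, which answer to the transcription factor SREBP2, mostly rose with E2. Of 20 measured, 12 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.52 (adjusted p = 3.39e-06, and adjusted p = 0.13 with an estimated correlation). ACAT2 rose by 1.24 ± 0.14, the sterol-binding protein gene TMEM97 by 0.81 ± 0.10, FDPS by 0.80 ± 0.10 and squalene epoxidase SQLE by 0.67 ± 0.090. Among fatty acid synthesis genes, 6 of 15 rose and 3 fell (7 and 3 adjusted over the list alone), among them the elongases ELOVL6 (0.70 ± 0.072) and ELOVL5 (0.70 ± 0.072), while the list as a whole was not called (median 0.21, adjusted p = 0.0971).

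Of 15 LXR targets, 5 fell (5 adjusted over the list alone) and the list moved down (median −0.12, adjusted p = 0.0138, and adjusted p = 0.19 with an estimated correlation). This call was lost without E2 replicate 2 (adjusted p = 0.0663) and with only members at or above the median level (0.0524), which left 8 of the 15. ABCG1, a cholesterol exporter, fell by 2.11 ± 0.19. Its relative ABCA1 was at least 3.26-fold lower by the group means (adjusted p = 0.00547), from a variable 4.91 ± 0.87 in vehicle to 3.20 ± 0.038 (SD, n = 3), near the lower quartile. In batch 2 ABCA1 differed less, at 3.98 in vehicle and 3.24 with E2. MYLIP, which marks the LDL receptor for degradation, fell by 0.69 ± 0.15 and NR1H3, which encodes LXRα, by 0.48 ± 0.080. Among nuclear receptors and coregulators 8 of 14 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of −0.31 (adjusted p = 0.0044, and adjusted p = 0.19 with an estimated correlation). The retinoid X receptor gene RXRA fell by 0.46 ± 0.072. The estrogen receptor gene ESR1 fell by 0.33 ± 0.071 (adjusted p = 0.0047), a call lost when its probe sets were averaged (adjusted p = 0.486).

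Interferon response genes were lower with E2: 11 of 23 fell (11 lower and 1 higher adjusted over the list alone, and 18 lower and 1 higher over all genes with the batch block), with a median of −0.59 (adjusted p = 1.34e-05, and adjusted p = 0.33 with an estimated correlation). IFI44L fell by 2.03 ± 0.39, the RNA sensor gene RIGI by 0.88 ± 0.18, IRF9 by 0.86 ± 0.14 and the peptide transporter gene TAP1 by 0.72 ± 0.13. The remaining lists were not called. The unfolded protein response list had 5 higher and 6 lower of 20 (adjusted p = 0.795), while CRELD2 rose by 0.49 ± 0.070 and the stress-induced factor gene DDIT3 fell by 0.51 ± 0.080. Epithelial genes had 1 higher and 3 lower of 19 (adjusted p = 0.249, 1 and 5 with the block), mesenchymal genes 2 lower of 17 (0.475, 1 higher and 3 lower with the block), hypoxia and glycolysis genes 1 higher and 4 lower of 18 (0.0999), p53 targets 2 higher and 4 lower of 15 (0.274), and retinoid and aryl hydrocarbon genes 2 higher and 3 lower of 14 (0.198). None of 16 markers of other cell types (adjusted p = 0.72) and none of 7 oxysterol and bile acid enzymes (0.988) was called, and with the block 1 of the 16 markers was lower. Among the members called were PMAIP1, a p53 target promoting apoptosis, which rose by 1.51 ± 0.14, and TIPARP, a target of the aryl hydrocarbon receptor, which rose by 0.88 ± 0.070. The 3' minus 5' signal of the ACTB control probe sets, a measure of RNA integrity and labelling, was lower in the 6 arrays with E2 (0.776) than in the 6 without (0.913; exact permutation p = 0.013, Benjamini-Hochberg adjusted 0.0433). It was lower in 6 of 6 pairs of arrays from a batch (exact p over 64 sign flips = 0.0312, the smallest they can give, adjusted 0.0781).

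**Figure D1:**
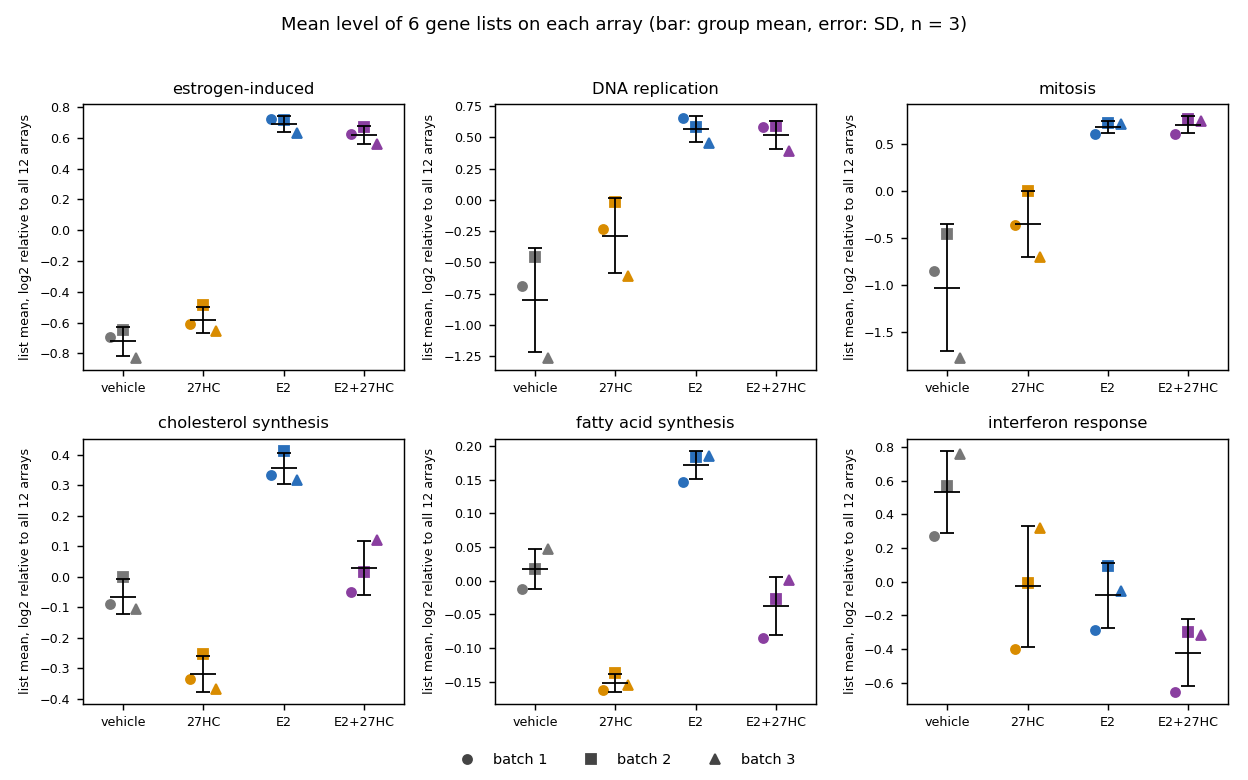
Mean log2 level of 6 gene lists in each array, relative to the mean of all 12 arrays, by treatment group; bars show group means, error bars the SD of 3 arrays and symbols the batch. Estrogen-induced genes stood at −0.72 in vehicle and −0.58 with 27HC against 0.69 with E2, whereas cholesterol synthesis genes stood at 0.36 with E2 and 0.028 with both compounds, and mitosis genes varied most between vehicle arrays (SD 0.67).

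The comparison of 27HC with vehicle asked what the oxysterol did without estrogen. Known estrogen reporters had small log2 differences from vehicle, 0.06 ± 0.17 for PGR (SE, adjusted p = 0.895), 0.06 ± 0.17 for GREB1 (0.906), −0.04 ± 0.093 for TFF1 (0.882) and 0.01 ± 0.078 for CXCL12 (0.981). Not every gene raised by E2 stayed near vehicle. MYBL1 stood at 7.14 ± 0.41 against 6.18 ± 0.84 and XBP1 at 10.55 ± 0.14 against 10.16 ± 0.064 (SD, n = 3), neither called. Over their probe sets the log2 differences ran from −0.101 to 0.959 for MYBL1 and from −0.0186 to 0.385 for XBP1. Of the 33 measured estrogen-induced genes, 23 had positive and 10 negative differences, with 0 called. PTGES, which encodes prostaglandin E synthase, rose 1.89-fold, from 5.45 ± 0.16 to 6.37 ± 0.092 (SD, n = 3). LPIN1, a phosphatidate phosphatase gene of lipid synthesis, fell by 0.56 ± 0.067, from 7.91 ± 0.0068 to 7.35 ± 0.070. With every probe set tested on its own, 1 of 2 for PTGES was called (log2 differences 0.0872 to 0.922). For LPIN1 it was 1 of 3 (−0.57 to −0.208). As groups, DNA replication and mitosis genes had higher medians with 27HC (0.49 and 0.68), and genes of cholesterol synthesis, fatty acid synthesis and the interferon response lower ones (−0.27, −0.20 and −0.56). All 5 lists were called at the preset correlation, and of these only fatty acid synthesis with an estimated correlation (adjusted p = 0.034).

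These 2 genes were the only ones limma called, 1 higher and 1 lower, while 2786 genes had an unadjusted p under 0.05. With the batch as a block, 240 genes were called, 84 higher and 156 lower, and 0, 0 and 20 when batch 1, 2 or 3 was left out. PTGES had an adjusted p of 0.0133 (0.00505 with the block) and was lost without 27HC replicate 2 (adjusted p = 0.0737). LPIN1 had an adjusted p of 0.0139 (0.00505 with the block) and lost its call without any 1 of the 6 arrays compared (adjusted p = 0.167 and 0.0699 and 0.0602 without 27HC replicates 1 to 3, and 0.0717 and 0.05 and 0.109 without vehicle replicates 1 to 3). With the block, both were lost without batch 1, 2 or 3 (adjusted p = 0.0964, 0.0844 and 0.0522 for PTGES, and 0.367, 0.0948 and 0.0522 for LPIN1). Both calls were also lost when only the 6 arrays compared were fitted (adjusted p = 0.138 for PTGES and 0.232 for LPIN1). The number of called genes was 1 without 27HC replicate 1, 0 without 27HC replicate 2 and 1 without vehicle replicate 3.

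All 38 DNA replication genes had a positive difference from vehicle, with a median of 0.49 (adjusted p = 5.95e-20, and adjusted p = 0.25 with an estimated correlation). None of the 38 was called over all genes, 26 were called adjusted over the list alone, and with the block 13 were called over all genes. FEN1 stood 0.52 ± 0.13 above vehicle (adjusted p = 0.203, block 0.0272) and E2F2 0.57 ± 0.14 (0.196, block 0.0453). All 35 mitosis genes were likewise positive, with a median of 0.68 (adjusted p = 2.82e-18, and adjusted p = 0.26 with an estimated correlation), 0 called over all genes (1 with the block) and 27 adjusted over the list alone. KIF23 stood 0.84 ± 0.21 above vehicle (0.206, block 0.0496) and FOXM1 0.74 ± 0.22 (0.238). Within batches the mean difference of the mitosis genes was 0.487, 0.464 and 1.07.

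Of 20 cholesterol synthesis genes 16 were lower with 27HC, with a median of −0.27 (adjusted p = 4.88e-08, and adjusted p = 0.096 with an estimated correlation). None was called over all genes (4 with the block) and 12 were called adjusted over the list alone. INSIG1, a sterol-regulated brake on SREBP processing, differed by −0.62 ± 0.11 (adjusted p = 0.134, block 0.00505), LSS by −0.51 ± 0.094 (0.134, block 0.0126), MSMO1 by −0.46 ± 0.11 (0.206, block 0.0149) and IDI1 by −0.45 ± 0.11 (0.196, block 0.0275). The fatty acid synthesis list moved down (median −0.20, adjusted p = 5.04e-05, 0.034 with an estimated correlation and 0.089 with an estimated correlation and the block). Of its 15 genes LPIN1 was called (2 genes with the block), and 7 were adjusted over the list alone. The desaturase gene SCD differed by −0.57 ± 0.091 (adjusted p = 0.107, block 0.00505), FASN by −0.36 ± 0.085 (0.196) and ACACA by −0.29 ± 0.069 (0.196).

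All 23 interferon response genes were lower with 27HC, with a median of −0.56 (adjusted p = 2.43e-11, and adjusted p = 0.23 with an estimated correlation), 0 called over all genes, 12 adjusted over the list alone, and with the block 12 over all genes and 20 adjusted over the list alone. TAP1 differed by −0.56 ± 0.13 (adjusted p = 0.196, block 0.0149), RIGI by −0.74 ± 0.18 (0.204, block 0.0235), IFIH1 by −0.79 ± 0.22 (0.224, block 0.0272) and IFIT3 by −1.08 ± 0.30 (0.224, block 0.0235). The 3 probe sets of RIGI ranged from −0.739 to 0.127. The estrogen-induced list stood slightly higher (median 0.08, adjusted p = 0.0196, and adjusted p = 0.23 with an estimated correlation, 0 of 33 called over all genes and 0 adjusted over the list alone), a call lost without 27HC replicate 2 (adjusted p = 0.139) or vehicle replicate 3 (0.106). With the block 1 member was called over all genes, PKIB, a protein kinase inhibitor gene (0.635 ± 0.20, adjusted p = 0.238, block 0.0272), and 6 adjusted over the list alone. The estrogen-repressed list stood lower (median −0.18, adjusted p = 2.05e-04, and adjusted p = 0.23 with an estimated correlation, 0 of 20 called over all genes and 3 adjusted over the list alone). With the block 1 member was called over all genes, the adaptor gene BLNK (−0.84 ± 0.16, adjusted p = 0.158, block 0.0275), and 7 adjusted over the list alone. The p53 targets moved by a median of −0.15 (adjusted p = 0.00369, and adjusted p = 0.26 with an estimated correlation, 0 called over all genes and 0 adjusted over the list alone, 4 of these with the block), a call lost without 27HC replicate 1 (adjusted p = 0.057) or vehicle replicate 3 (0.156) and with only members at or above the median level (0.122). All 15 measured members lay at or above the median level, so the last loss did not come from dropped members.

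LXR targets were not called with 27HC (median −0.09, adjusted p = 0.132), with 0 of 15 lower over all genes (2 with the block) and 1 adjusted over the list alone (2 with the block). The log2 difference was −0.09 ± 0.38 for ABCA1 (SE, adjusted p = 0.935), −0.42 ± 0.19 for ABCG1 (0.338) and −0.38 ± 0.15 for MYLIP (0.302, block 0.0481). ESR1 differed by −0.24 ± 0.071 (0.238). The 6 arrays with 27HC had lower hybridisation controls than the 6 without (10.03 against 10.24, exact permutation p = 0.00433, adjusted 0.0325) and a lower array SD (2.34 against 2.38, exact permutation p = 0.00649, adjusted 0.0325). The poly-A controls were lower as well, a difference that failed the correction (7.025 against 7.227, exact permutation p = 0.0346, adjusted 0.0866). Each of the 3 measures was lower with 27HC in 6 of 6 pairs of arrays from a batch (exact p over 64 sign flips = 0.0312, adjusted 0.0781). These differences run along with every gene group compared between arrays with and without 27HC, the lipid, cell cycle and interferon lists included.

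**Figure D2:**
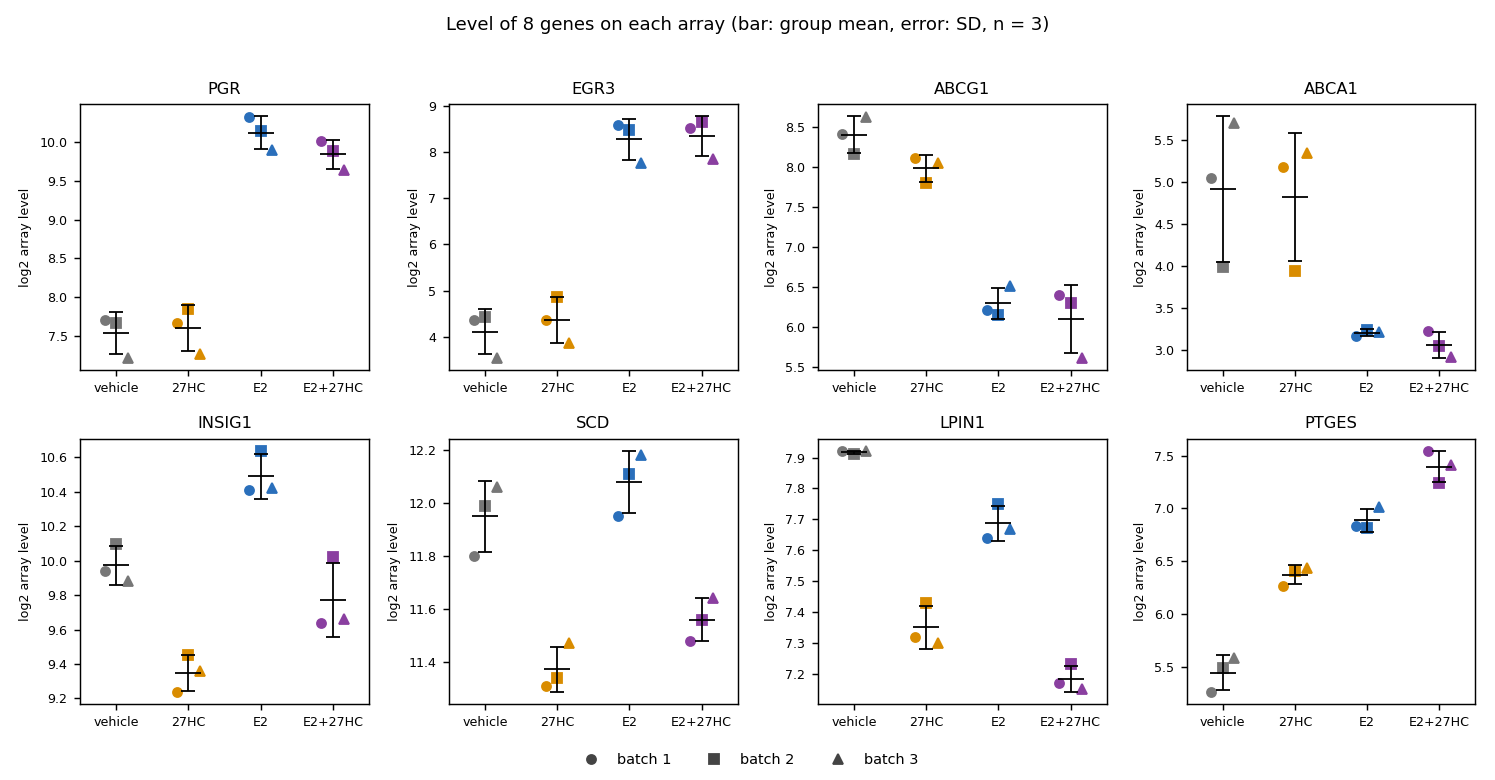
Log2 expression of PGR, EGR3, ABCG1, ABCA1, INSIG1, SCD, LPIN1 and PTGES in each of the 12 arrays by group, with the group mean and SD (n = 3); symbols mark the batch. EGR3 rose from 4.11 in vehicle to 8.28 with E2, INSIG1 stood at 9.97 in vehicle, 9.35 with 27HC, 10.49 with E2 and 9.77 with both, and ABCA1 varied widely in vehicle (SD 0.87).

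The comparison of both compounds with E2 alone asked whether 27HC altered the estrogen response. Cholesterol and fatty acid synthesis genes were lower when 27HC was added (list medians −0.36 and −0.21, adjusted p = 0.02 and 0.0041 with an estimated correlation). The estrogen reporters were not called, at −0.28 ± 0.17 for PGR (SE, adjusted p = 0.529), −0.29 ± 0.17 for GREB1 (0.517), 0.04 ± 0.093 for TFF1 (0.91) and −0.33 ± 0.078 for CXCL12 (0.255). INSIG1 stood at 9.77 ± 0.21 with both compounds against 10.49 ± 0.13 with E2, and SCD at 11.56 ± 0.080 against 12.08 ± 0.12 (SD, n = 3).

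Limma called 0 genes, with 2279 at an unadjusted p under 0.05. The count was 12 with the batch block (2 higher, 10 lower, and 0 when any 1 batch was left out), 4 with a trend and robust prior, 1 among genes at or above the median level or at or above a mean log2 of 6, and 15 with array weights. The block calls included 4 named lipid genes, INSIG1 (−0.72 ± 0.11, adjusted p = 0.152, block 0.00843), MSMO1 (−0.62 ± 0.11, 0.201, block 0.00847), SCD (−0.52 ± 0.091, 0.201, block 0.0113) and LPIN1 (−0.51 ± 0.067, 0.0867, block 0.0113). They also included LSS (−0.46 ± 0.094, 0.216, block 0.0492), which makes lanosterol. HMGCS1, the HMG-CoA synthase gene, differed by −0.54 ± 0.097 (0.201).

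Of 20 cholesterol synthesis genes 19 were lower, with a median of −0.36 (adjusted p = 3.68e-13, 0.02 with an estimated correlation and 0.08 with an estimated correlation and the block), 0 called over all genes (3 with the block) and 13 adjusted over the list alone. Of 15 fatty acid synthesis genes 13 were lower, with a median of −0.21 (adjusted p = 1.32e-08, 0.0041 with an estimated correlation), 0 called over all genes (2 with the block) and 7 adjusted over the list alone. Interferon response genes stood lower by a median of −0.30 (adjusted p = 4.36e-05, and adjusted p = 0.57 with an estimated correlation), with 22 of 23 negative, 0 called over all genes, 0 adjusted over the list alone, and with the block 14 lower and 1 higher adjusted over the list alone. IFIH1 differed by −0.75 ± 0.22 (0.299). The p53 targets had a median of −0.13 (adjusted p = 0.00711, and adjusted p = 0.57 with an estimated correlation, 0 called over all genes and 0 adjusted over the list alone, 1 of these with the block), a call lost without replicate 1 of the combined group (adjusted p = 0.0729), with only members at or above the median level (0.157) and after a second quantile normalization (0.11). The level setting dropped none of the 15 measured members. DNA replication (median −0.05, adjusted p = 0.485), mitosis (0.02, 0.914) and estrogen-induced genes (−0.05, 0.0567) were not called as lists, and with the block 1 estrogen-induced gene was lower.

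The comparison of both compounds with 27HC alone asked what E2 did in the presence of the oxysterol. EGR3 rose 15.7-fold, PGR 4.75-fold, CXCL12 3.24-fold, TFF1 2.78-fold and GREB1 2.70-fold. MYBL1 rose 6.87-fold, PDZK1 6.26-fold, CDH26 5.80-fold, VXN at least 5.29-fold (adjusted p = 9.5e-06) and RBM24 5.13-fold. IL1R1 was at least 6.2-fold lower (adjusted p = 1.17e-06), AHRR 5.60-fold, WNT2B 5.32-fold, ASB9 4.11-fold, IFI44L 3.89-fold and DDIT4, a stress-induced inhibitor of mTOR signalling, 3.72-fold. ABCG1 fell by 1.88 ± 0.19 (SE), and ABCA1 was at least 3.05-fold lower (adjusted p = 0.00826). VXN with 27HC alone, and IL1R1 and ABCA1 with both compounds, lay near or below the lower quartile of array levels. Their bounds are those of the group means. In batch 2 ABCA1 stood at 3.94 with 27HC and 3.04 with both compounds.

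Of 33 estrogen-induced genes 27 rose (29 higher and 2 lower adjusted over the list alone; median 1.18, adjusted p = 1.42e-29, 0.00024 with an estimated correlation), and of 20 estrogen-repressed genes 16 fell (17 adjusted over the list alone; median −0.98, adjusted p = 5.07e-20, 0.0092 with an estimated correlation and 0.063 with an estimated correlation and the block). DNA replication genes rose in 33 of 38 cases (38 adjusted over the list alone), with a median of 0.80 (adjusted p = 5.07e-20, and adjusted p = 0.23 with an estimated correlation), FEN1 by 0.87 ± 0.13 and LIG1 by 0.83 ± 0.13. Mitosis genes rose in 34 of 35 cases (35 adjusted over the list alone), with a median of 1.06 (adjusted p = 1.84e-18, and adjusted p = 0.23 with an estimated correlation), FOXM1 by 1.11 ± 0.22 and CDCA8 by 1.23 ± 0.24. Of cholesterol synthesis genes 10 of 20 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.34, adjusted p = 3.45e-06, and adjusted p = 0.13 with an estimated correlation), SQLE by 0.60 ± 0.090 and the last enzyme of the pathway, DHCR7, by 0.68 ± 0.10.

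LXR targets had 2 of 15 lower (3 adjusted over the list alone, and with the block 5 over all genes and 5 over the list alone; median −0.10, adjusted p = 0.0133, and adjusted p = 0.23 with an estimated correlation), a call lost with only members at or above the median level (0.0887), which left 8 of the 15. Nuclear receptors and coregulators had 1 higher and 6 lower of 14 (1 and 7 adjusted over the list alone; median −0.18, adjusted p = 5.17e-04, and adjusted p = 0.17 with an estimated correlation). RXRA fell by 0.48 ± 0.072 and the coactivator gene NCOA1 fell by 0.43 ± 0.095. Interferon response genes had 3 lower of 23 (8 adjusted over the list alone, and with the block 11 lower and 1 higher over all genes, 12 and 2 over the list alone; median −0.37, adjusted p = 0.00185, and adjusted p = 0.5 with an estimated correlation), a call lost without 27HC replicate 3 (adjusted p = 0.0773). Limma called 2969 genes, 1662 higher and 1307 lower (15% of those tested), with the same sign in all 3 batches for 2966. The count was 1702 without 27HC replicate 1 and 1471 without 27HC replicate 3.

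The interaction asked whether the 27HC difference depended on E2. The cell cycle lists had the largest interactions in size: with 27HC they stood above vehicle in the absence of E2, and in its presence neither list was called. The DNA replication list had a median interaction of −0.55 (adjusted p = 1.79e-25, and adjusted p = 0.5 with an estimated correlation), with all 38 genes negative, and the mitosis list one of −0.65 (adjusted p = 1.01e-18, and adjusted p = 0.59 with an estimated correlation), with all 35 negative. The replication clamp gene PCNA had an interaction of −0.70 ± 0.27 (SE), CDK1 of −0.93 ± 0.34 and KIF23 of −0.91 ± 0.30, each with an adjusted p of 0.998. The estrogen-induced list had a median of −0.15 (adjusted p = 4.11e-06, and adjusted p = 0.067 with an estimated correlation), with SERPINA1 at −0.56 ± 0.18. The interferon list had a median of 0.22 (adjusted p = 0.00927, and adjusted p = 0.7 with an estimated correlation), a call lost without replicate 2 (adjusted p = 0.156) or 3 (0.0509) of the combined group, 27HC replicate 1 (0.697), E2 replicate 1 (0.296) or vehicle replicate 3 (0.435). Cholesterol synthesis (median −0.09, adjusted p = 0.143) and fatty acid synthesis (0.454) were not called.

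No single gene passed the interaction test: limma called 0 genes, 0 with the block, and 767 had an unadjusted p under 0.05 (1452 with the block). Adjusted over each list alone, 0 genes of any list were called; with the block 32 of 38 DNA replication genes and 7 of 33 estrogen-induced genes were lower and 2 of 15 LXR targets higher, adjusted over the list alone. The standard error of an interaction was larger, with a median of 0.14.

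The direct comparison of 27HC with E2 set the 2 sterol ligands side by side, at doses that differ (1 µM and 1 nM). EGR3 was 15.1-fold lower with 27HC, PDZK1 7.47-fold, MYBL1 7.09-fold, CDH26 6.51-fold, PGR 5.76-fold, CXCL12 4.08-fold, GREB1 3.31-fold and TFF1 2.71-fold. IL1R1 was at least 6.57-fold higher (adjusted p = 8.21e-07), AHRR 5.49-fold, CDK6 4.27-fold and ASB9 3.75-fold. Of 33 estrogen-induced genes 27 were lower and 1 higher (28 and 2 adjusted over the list alone; median −1.26, adjusted p = 6.3e-31, 2e-04 with an estimated correlation), and of 20 estrogen-repressed genes 16 were higher (17 adjusted over the list alone; median 0.87, adjusted p = 9.94e-16, 0.01 with an estimated correlation and 0.057 with an estimated correlation and the block). Among the latter were ERBB2, which encodes the HER2 receptor (0.76 ± 0.080, SE), and YPEL3 (1.03 ± 0.094).

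DNA replication genes were lower in 37 of 38 cases (38 adjusted over the list alone; median −0.86, adjusted p = 1.17e-21, and adjusted p = 0.22 with an estimated correlation) and mitosis genes in 33 of 35 (35 adjusted over the list alone; median −1.01, adjusted p = 6.36e-18, and adjusted p = 0.27 with an estimated correlation). Cholesterol synthesis genes were lower in 16 of 20 cases (17 adjusted over the list alone; median −0.73, adjusted p = 1.48e-14, 0.01 with an estimated correlation and 0.057 with an estimated correlation and the block). INSIG1 differed by −1.14 ± 0.11, IDI1 by −1.06 ± 0.11, DHCR7 by −1.02 ± 0.10 and SQLE by −0.92 ± 0.090. Fatty acid synthesis genes were lower in 8 of 15 cases (9 adjusted over the list alone; median −0.34, adjusted p = 1.85e-06, 0.0074 with an estimated correlation), with ELOVL6 at −0.91 ± 0.072 and SCD at −0.70 ± 0.091. Nuclear receptors and coregulators had 4 higher and 1 lower of 14 (9 and 1 adjusted over the list alone, and 8 and 1 over all genes with the block; median 0.25, adjusted p = 0.00473, and adjusted p = 0.22 with an estimated correlation). ABCG1 was 3.23-fold higher with 27HC than with E2, and ESR1 differed by 0.09 ± 0.071 (adjusted p = 0.434).

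Limma called 3044 genes between 27HC and E2, 1083 higher and 1961 lower with 27HC (15.4% of those tested), with the same sign in all 3 batches for 3042. The count was 1756 without 27HC replicate 1, 1524 without 27HC replicate 3, 1814 without E2 replicate 1 and 1699 without E2 replicate 2. The share of calls that were higher with 27HC was 35.6%, against 25% with arrays centred on their medians and 49.7% after a second quantile normalization, so the balance of directions depended on the scaling. Neither rescaling moved the median of all genes by 0.1.

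**Figure D3:**
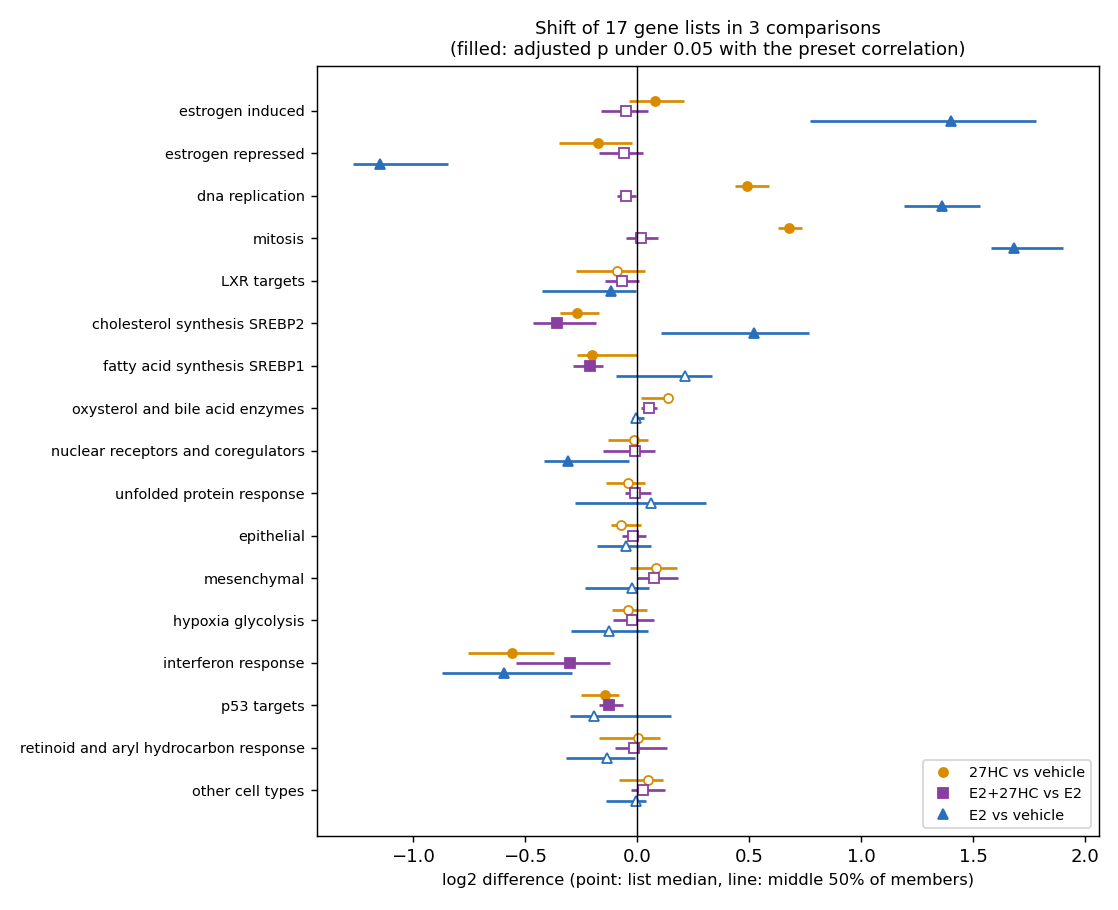
Log2 difference of 17 gene lists for 27HC against vehicle, both compounds against E2, and E2 against vehicle; points are list medians, lines the middle 50% of members, and filled points had an adjusted p under 0.05 at the preset correlation. Cholesterol synthesis genes were lower with 27HC in both backgrounds (medians −0.27 and −0.36) and higher with E2 (0.52), whereas mitosis genes had a median of 0.68 with 27HC alone and 0.02 with both compounds against E2.

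Across genes, which are not independent replicates, the log2 differences of E2 against vehicle and of both compounds against 27HC, which share no arrays, had a correlation of 0.896 (0.000469 in simulated unchanged groups). They shared 1418 genes called higher, where independent lists would share 182, and 1142 called lower, where they would share 138. The differences of 27HC with and without E2, which also share no arrays, had a correlation of 0.466 (0.000469 simulated), with the same sign in 67% of genes (50.1% simulated). After a second quantile normalization these values were 0.41 and 63.2%. The simulation holds no technical shift shared by the 27HC arrays, and it draws each gene independently. Measured genes vary together: with group means removed, arrays of different groups correlated from −0.47 to 0.55. The simulated values therefore do not show how far chance alone could take these correlations. The differences of 27HC and of E2 from vehicle had a correlation of 0.611, against 0.501 in simulated unchanged groups that share the vehicle arrays. The same-sign share was 66.6%, and also 66.6% in the simulated groups. The covariance was 0.0384 against a simulated 0.00644, a difference of 0.0319. PTGES and LPIN1, the 2 genes called with 27HC, were called in the same direction with E2. With the block, 74 genes were higher in both (11.2 by chance) and 129 lower in both (20.8 by chance). The 3 vehicle arrays could not be split into sets of 2, so part of the excess overlap may come from the shared controls. Genes called at least 2-fold changed with E2 in 2 batches were therefore measured in the batch left out, so that no array served both to choose and to measure. Outside the cell cycle lists, the genes chosen as higher with E2 differed from vehicle with 27HC by a mean of 0.28, 0.307 and 0.484 in batches 1 to 3, and those chosen as lower by −0.484, −0.268 and −0.387. With E2 present, 27HC shifted the former by −0.136, −0.0259 and −0.0508 and the latter by −0.246, −0.0837 and −0.117. Only members of the cell cycle lists (73 genes) were set aside, so other genes that follow growth may remain among those chosen.

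Median, mean and test of a list differed in sign only for lists that were not called. These were retinoid and aryl hydrocarbon genes and markers of other cell types for 27HC against vehicle, oxysterol and bile acid enzymes for E2 against vehicle, unfolded protein response and retinoid and aryl hydrocarbon genes for both compounds against E2, other cell types for both compounds against 27HC, LXR targets, fatty acid synthesis and mesenchymal genes in the interaction, and unfolded protein response, epithelial genes and p53 targets for 27HC against E2.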

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

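The tests of the cell cycle pattern were chosen after the list shifts had been seen, as were the label swaps within batches for the interaction, while the other comparisons with splits of the samples were planned.

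The response to 27HC differed between cells without and with E2 in 4 gene lists, by the interaction test at the preset correlation. The median log2 interaction was −0.653 for mitosis genes, −0.55 for DNA replication genes, −0.152 for estrogen-induced genes and 0.218 for interferon response genes, and with an estimated correlation none of the 4 was called. The interferon call was lost without replicate 2 (adjusted p = 0.156) or 3 (0.0509) of the combined group, 27HC replicate 1 (0.697), E2 replicate 1 (0.296) or vehicle replicate 3 (0.435). Over 100 of the 200 splits of the 27HC labels within the arrays with and without E2, 62 gave at least the 4 lists called for the interaction, with up to 11 in another split, so chance was not excluded for the number of lists. Of the 32 splits that swap the labels only within batches and so keep the pairing, 21 gave at least 4 lists, with up to 9 in another split. For single genes the real split gave 0 calls and all 100 and all 32 splits gave as many. The highest other split gave 144 in both sets, and it is by construction the averaged contrast of all arrays with 27HC against all without.

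The 73 cell cycle genes stood higher with 27HC than with vehicle in the absence of E2, by a mean log2 of 0.471, 0.451 and 0.855 in the 3 batches. A separate processing of the 27HC arrays that shifts both backgrounds equally would show with E2 present too. There the mean shift was −0.0116 (−0.0406, 0.0225 and −0.0167 by batch). This difference between backgrounds is the interaction, which camera did not call with an estimated correlation (adjusted p = 0.5 for DNA replication and 0.59 for mitosis). Separate processing is therefore not excluded. Whether 27HC had an E2-like action of equal share on all E2-regulated genes is not decided. 27HC reached at most 11.8% of the E2 shift in the estrogen-induced list (6.02%, 11.6% and 11.8%) against 33.6%, 40.6% and 41% in the cell cycle genes. Both shifts of a batch subtract the same vehicle array, so a low vehicle array raises the share. Vehicle arrays varied more in mitosis (SD 0.67) and DNA replication genes (0.41) than in the estrogen-induced list (0.094). A difference in growth between single cultures cannot be told apart from an effect of 27HC, since the smallest share that 8 label swaps within batches allow is 0.25 and the real labels gave it. A weaker E2-like action, of equal or unequal share, stays open. E2-induced genes chosen in the other 2 batches, outside the cell cycle lists, differed from vehicle with 27HC by 0.28, 0.307 and 0.484 (1.41, 1.18 and 1.7 with E2). E2-repressed ones differed by −0.484, −0.268 and −0.387 (−1.41, −1.02 and −1.57 with E2). Here too 3 batches allow no share under 0.25. Only members of the cell cycle lists (73 genes) were left out, so other genes that follow growth may remain among those chosen. In the same batches the fixed estrogen-induced list differed from vehicle with 27HC by 0.0851, 0.158 and 0.171 (1.42, 1.36 and 1.46 with E2).

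Probe sets outside the gene-level comparisons also responded to E2. Of 13522 probe sets that name no gene or several, counted without 56 such control probe sets, 476 were higher and 926 lower with E2 than with vehicle, 74 and 94 of them at least 2-fold, and 1 was called for 27HC against vehicle.

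The 6 arrays of a pair of groups can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2 genes for 27HC against vehicle (1 of the 10 splits reached as many, and the highest other gave 0), 4260 for E2 against vehicle (1 of 10, other 0), 2969 for both compounds against 27HC (1 of 10, other 0), 3044 for 27HC against E2 (1 of 10, other 0) and 0 for both compounds against E2 (10 of 10, other 1). For lists called, it gave 8 for 27HC against vehicle (2 of the 10 splits reached as many, and the highest other gave 9), 8 for E2 against vehicle (2 of 10, other 8), 4 for both compounds against E2 (3 of 10, other 5), 8 for both compounds against 27HC (4 of 10, other 9) and 7 for 27HC against E2 (6 of 10, other 9). Because the batches pair the arrays, the 3 other splits that also part every pair are the closest comparison. They called 0 genes in all of these contrasts. They called 1, 5 and 6 lists for 27HC against vehicle, 4, 8 and 6 for E2 against vehicle, 3, 0 and 0 for both compounds against E2, 3, 8 and 8 for both compounds against 27HC, and 6, 9 and 6 for 27HC against E2. Every other split holds 2 arrays of a group against 1, so part of the treatment difference remains in its counts.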

How the results depend on the processing

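The block with an estimated correlation, the block without a batch, the rescalings of the lists, the quantile normalization for the correlations and the averaged 27HC contrast were chosen after the data were seen, and the other alternatives were planned. The batch block moved the count for 27HC against vehicle from 2 to 240 and for both compounds against E2 from 0 to 12, and 33 calls of named genes were gained with it. It changed no other call of a named gene or list: all 102 list calls were the same. Over the alternatives, 7568 results of named genes were on the same side of the threshold with the same sign, 113 became calls, 294 lost their call and 1 changed sign. For the lists these numbers were 1810, 24, 92 and 0. The sign change was ACACA for E2 against vehicle, at −0.28 and at 0.0117 with the mean of its probe sets. Causes were not tested, beyond fewer genes, arrays or batches where the setting removes them.

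For 27HC against vehicle the count was 0 with only the groups compared, 7 with a trend and robust prior, 5 at a mean log2 of 6 or more, 4 with centred arrays, 5 with every probe set, 9 with the mean of probe sets, 7 with array weights, 0 with the minimum fold, and 0, 0 and 20 with the block without batch 1, 2 and 3. For both compounds against E2 it was 4 with a trend and robust prior, 1 at or above the median level, 1 at a mean log2 of 6 or more and 15 with array weights. With every probe set it was 8443 for E2 against vehicle, 5291 for both compounds against 27HC and 5204 for 27HC against E2, where more features are tested. With the minimum fold it was 1394, 441 and 477. With the block without batch 1 it was 1843 for both compounds against 27HC and 1687 for 27HC against E2, and array weights gave 5386 for the latter. The averaged 27HC contrast called 144 genes, 1207 with the block, 43 after quantile normalization, and 8, 3 and 362 with the block without batch 1, 2 and 3.

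Without 1 array, counts ran from 0 to 3 for 27HC against vehicle, 3167 to 4606 for E2 against vehicle, 0 to 0 for both compounds against E2, 1471 to 3054 for both against 27HC, 0 to 0 for the interaction, 1524 to 3438 for 27HC against E2 and 4 to 339 for the averaged 27HC contrast. In the same order of the first 6, lists called ran from 6 to 8, 7 to 9, 3 to 6, 7 to 8, 3 to 6 and 7 to 10. With an estimated correlation 1, 2, 2, 2, 0 and 4 lists were called, and 0, 1, 1, 1, 0 and 2 with the block as well. fry called 2 for 27HC against vehicle, 2 for both compounds against E2 and 0 for the interaction. Centred arrays added mesenchymal genes for 27HC against E2, and quantile normalization ended the p53 call for both compounds against E2. The correlation of the 27HC and E2 differences was 0.734 at or above the median level and 0.511 by Spearman (0.477 to 0.708 without 1 array), that of the E2 differences 0.943 and 0.721 (0.857 to 0.91), and that of the 27HC differences 0.367 to 0.507 without 1 array and 0.41 after quantile normalization. The number of arrays limits what was detectable, as do levels near background, where RMA shrinks differences.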

Other observations

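The averaged 27HC contrast, its genes and every test in this part were chosen after the results had been seen, except the comparison with 100 splits of the samples, which was set before its own result.

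Averaged over both backgrounds, the 6 arrays with 27HC differed from the 6 without in 144 genes, 29 higher and 115 lower (4206 at an unadjusted p under 0.05). LPIN1 differed by −0.53 ± 0.047 (SE, adjusted p = 9.43e-04), INSIG1 by −0.67 ± 0.078 and SCD by −0.55 ± 0.064 (0.00577 each), LSS by −0.49 (0.0201), MSMO1 by −0.54 (0.0265), HMGCS1 by −0.42 (0.0322) and IDI1 by −0.42 (0.0352). Of the lists, 7 of 20 cholesterol synthesis genes (13 with the block, adjusted p of the list = 0.028 with an estimated correlation, 0.11 with the block as well), 5 of 15 fatty acid synthesis genes (7 with the block, 0.0067 and 0.023), 2 of 20 estrogen-repressed genes (4 with the block, 0.31 and 0.42), 2 of 23 interferon response genes (18 with the block, 0.31 and 0.13) and 1 of 16 markers of other cell types (1 higher and 1 lower with the block, 0.64 and 0.63) were called lower. With the block, calls in lists without any were DNA replication (3 higher), mitosis (1 higher), LXR targets (3 lower), retinoid and aryl hydrocarbon genes (2 lower), nuclear receptors and coregulators and p53 targets (1 lower each), and estrogen-induced and mesenchymal genes (1 higher and 1 lower each). PTGES was higher by 0.72 ± 0.073 (adjusted p = 0.00228), and each of these genes had the same sign in 6 of 6 pairs of arrays from a batch. The genes were called on the same arrays, so the shared sign adds no separate support. Over 100 of the 200 splits of the 27HC labels within the arrays with and without E2, 1 reached 144, the real one, and the highest other gave 15. Chance alone is therefore unlikely to give this count, though it is not excluded. The splits cannot tell a 27HC effect from separate processing of the 27HC arrays. Of the 32 splits that swap labels only within batches, the real one alone reached 144 and the highest other gave 0. The count was 4, 7 and 99 without 27HC replicates 1 to 3, 8, 339 and 6 without vehicle replicates 1 to 3, 11, 6 and 267 without E2 replicates 1 to 3, and 24, 155 and 39 without replicates 1 to 3 of the combined group.

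Other genes lower with 27HC in this contrast came from outside the lipid lists. The interferon-induced genes CMPK2 (−1.03, adjusted p = 0.0388), IFIH1 (−0.77, 0.0454), RIGI (−0.63, 0.0472) and BST2 (−0.55, 0.04) were lower, as were the histone genes H3C6 (−0.61) and H2BC4 (−0.53), the collagen gene COL1A1 (−0.60, 0.0322), the adaptor gene BLNK (−0.72, 0.0316) and QPRT (−0.68), an enzyme gene of NAD synthesis. STON2 (0.61), FOXI1 (0.43) and TIAM1 (0.41), an activator of RAC signalling, were higher. In the direct comparison of both compounds with E2, the genes called with the block outside the lipid lists were RUSC1-AS1 (−0.79), BRINP3 (−0.76), QPRT (−0.62), SERPINA1 (−0.60) and TMT1A (−0.53), lower, and C1orf105 (0.50) and DHRS2 (0.54), higher.

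Sterol and fatty acid synthesis genes were lower with 27HC in both backgrounds, with a median log2 difference of −0.251 over 35 genes. A compressed range of the 27HC arrays is argued against as the whole cause: 0% of 10000 lists matched on level lay at or below the median (matched median −0.042, lowest 2.5% at −0.0838). The 35 genes were taken up because their lists had been called lower, and the matched lists draw genes independently. The 0% is therefore no test of chance, and the argument rests on the small shift of the matched genes. After quantile normalization 74.6% of the difference was kept. That share adds little, because normalization shifts genes of a given level by too little to remove most of the difference. With an estimated correlation the cholesterol list lost its call after that normalization (adjusted p = 0.062, from 0.028) as its difference shrank from a median of −0.296 (middle 50% of genes −0.42 to −0.193) to −0.255 (−0.362 to −0.127), and the fatty acid list was called at 0.049. Lower growth would lower the cell cycle genes. With 27HC they stood higher without E2, by at least 0.451 in every batch, and moved little with E2 (−0.0406, 0.0225 and −0.0167 by batch). This absence of a fall argues against lower growth in these samples, unless separate processing of the 27HC arrays hid a fall. The rise itself was not called by camera with an estimated correlation (adjusted p = 0.25 for DNA replication and 0.26 for mitosis). Separate processing cannot be told apart from a 27HC effect, since the array numbers in the titles run from 16 to 96 without 27HC and all lie above these with it, and the hybridisation controls differed by −0.207 and the poly-A controls by −0.202, both lower in 6 of 6 pairs from a batch.

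Of the genes called in the averaged contrast, 21 of 29 higher ones (72.4%) lay below the median level of all genes, against 16 of 115 lower ones (13.9%, Fisher's exact test, two-sided p = 2.08e-09). That test treats genes as independent, which genes measured on the same arrays are not, so its p-value overstates the evidence. Array levels were compressed with 27HC. The higher genes kept 98.6% of their median difference after quantile normalization (0.337 before with a median SE of 0.0645, 0.332 after with 0.0612). With all genes grouped by level from 1 (lowest) to 10, median 27HC differences were 0.0369 to 0.0822 in level groups 1 to 5. They were −0.0653 to −0.0298 in level groups 6 to 10. Normalization moved the largest, 0.0822 in level group 3, to 0.0346. Removing shifts this small could not take most of 0.337 away, so the share kept does not test compression. The array-wide shift was smaller but ran the same way, so compression stays open as a cause of the split by level. Of the higher calls 9 of 29 were kept after normalization, and 33 of 115 of the lower ones, as the number of genes at an unadjusted p under 0.05 went from 4206 to 3464. A first version of the comparison before and after normalization counted calls kept and was replaced by the size after its result had been seen. No biological explanation was tested.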
